A study of Mus musculus with 2 samples.

How the data were processed

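Total RNA of C2C12 cells was measured on 2 arrays, 1 per group. C2C12 is a mouse myoblast line that fuses into myotubes in low serum, and per the labels' protocols the myotubes were used. One culture received 4 µg of exosomes from a KPC line, a mouse pancreatic cancer line, for 24 h. The control culture received exosomes of a mouse pancreatic ductal epithelial line (MPDC-exo), whose dose is not given in the sources used here. The groups follow the treatment given in the labels. With 1 array per group there is no replicate, so no test was run and no p-value is given.

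Per the labels, the RNA was amplified to Cy3-labelled cRNA with a 1-colour Agilent kit. Per the file headers and the submitters' processing notes, the spots were read with Agilent Feature Extraction 10.7.1.1, which subtracted the background and removed spatial trends on each array and replaced small values by a surrogate. The deposited scanner files hold spot intensity on a linear scale, not normalized between the arrays. Each holds 62976 features, of which 59305 are not control spots and represent 56605 distinct probes of 60 bases. Both arrays lay on 1 slide and were read in 1 scan, so slide and scan do not differ between the groups. Probe positions are on mm9, per the file headers. The series value table holds log2 values whose making the authors did not state in the sources used here. Set against each array's own scanner values they correlated across probes at 1.00 in both columns. The sorted columns differed by at most 0.000481 and both had a median of 4.88, as quantile normalization of the log2 signal would give. That table is on the log2 scale and is not centred per gene, and it was used only as an alternative.

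For the main values, log2 of the processed signal was taken, spots flagged as non-uniform or as population outliers were left out, the spots of a probe were averaged, and each array's 75th percentile over its probes was subtracted. The flags removed 102 spots on the MPDC-exo array and 166 on the KPC-exo array. No spot was saturated. Of the 56578 probes with a value on both arrays, 45.9% were well above background on the MPDC-exo array and 47.6% on the KPC-exo array. Because this is just under the majority, the percentile was also taken over the probes detected on both arrays, as an alternative chosen after seeing the data. A gene was represented by its brightest probe and counted as measured where that probe was well above background on both arrays. A gene well above background on 1 array and, in all its probes, not on the other received only a bound. The bound sets the bright value against the higher of the lowest signal well above background on the other array and the probe's own signal there. The accessions of 32994 of the 56605 probes matched RefSeq names of the mouse assembly GRCm38.p6, which updated 1088 gene names, and other probes kept the name in the files. The reference was used for names only.

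Precision is limited by the number of arrays. The only error the files hold is technical. Of the 300 probes spotted 10 times, 292 were measured on both arrays, and their spots had a median SD of 0.03 on the log2 scale within either array. That value describes bright probes, since 280 of the 292 lay above the median signal of measured genes. The 12 dimmer probes had median SDs of 0.09 on the MPDC-exo array and 0.11 on the KPC-exo array. Between different probes of 1 gene the log2 difference had a pooled SD of 0.36 over 5767 genes with at least 2 measured probes. Neither value includes variation between cultures.

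Genes at least 2-fold apart between the arrays were counted. For each of 32 gene lists, the median log2 difference of its measured members was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these 2 arrays. Members at least 1.5-fold apart were counted, and a list with fewer than 5 measured members received no percentile. The genes named are the 12 highest and 12 lowest differences at or above the 25th percentile of signal whose measured probes all had the same sign, leaving out clone and predicted names; the 4 largest bounds in each direction; up to 4 members of each list with the largest difference; and a fixed set of muscle, insulin signalling and reference genes. The lists, this rule, the measures and most alternatives were fixed before the data were examined. Genes named outside the rule, chosen after their values were seen, are said to be so. Some genes that the rule selects are not reported here.

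The alternatives were normexp background correction with an offset of 50, centring on the median or on 7 spike-in probes, quantile and cyclic loess normalization, no filter or a stricter filter on dim probes, the mean over a gene's probes, flagged spots kept, the series value table, thresholds of 1.5-fold and 3-fold, and the mean of list members. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp, quantile and loess. The procedure was tested on simulated data made from the MPDC-exo array with spot noise of 0.03 log2 only. Of 67 genes changed 2.5-fold, 100% passed the 2-fold threshold in the right direction, as did 100% of 66 genes changed 4-fold and 0 of 67 changed 1.5-fold. None of 17302 unchanged genes (0) passed it among 17543 genes. That noise is the spread of bright probes and leaves out the larger spread of dim ones and differences between cultures and between labelling reactions.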

Results

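Gene expression was measured in C2C12 myotubes, a mouse skeletal muscle cell model, 24 h after addition of exosomes, the small vesicles that cells release. One culture received exosomes of KPC pancreatic cancer cells (KPC-exo) and the control culture received exosomes of pancreatic ductal epithelial cells (MPDC-exo). There was 1 array per group, so every difference below lies between 2 arrays and has no replicate check. The 75th percentile of the signal was 380 units on the MPDC-exo array and 639 units on the KPC-exo array. After each array was centred on that value, 16907 genes were measured on both, and their log2 signals correlated across genes at r = 0.99. Genes are not independent replicates.

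The comparison asks which genes differ in myotubes given cancer cell exosomes. Structural RNAs and some histone genes were among the genes with the lowest differences, while the mRNAs of muscle differed little. The classes of structural RNAs and replication-dependent histones were chosen after these values were seen. They hold 28 and 44 of the 16907 measured genes. Poorer labelling of RNAs without a poly(A) tail in the KPC-exo reaction stays open as an explanation, as set out below. Of the 57 genes at least 3-fold lower on the KPC-exo array, 8 were structural RNAs and 5 replication-dependent histones, and of the 201 at least 2-fold lower these numbers were 19 and 9. The U1 small nuclear RNA genes Rnu1b1, Rnu1b6 and Rnu1a1, whose product takes part in splicing, were 9.23-fold, 8.25-fold and 7.75-fold lower on the KPC-exo array. These genes are near-identical copies, and the probes of Rnu1b1 and Rnu1b6 overlap over nearly their whole length, so they are not separate measurements. The cell cycle list lay slightly lower as a group. In all, 123 genes were at least 2-fold higher and 201 lower on the KPC-exo array, while 98.1% of the measured genes lay within 2-fold. These counts depend on the treatment of dim signal, being 31 and 106 with normexp background correction, 7 and 44 with a stricter filter on dim probes, and 1600 and 1427 with no such filter. Of the 123 higher genes, 101 were among the 25% of measured genes with the lowest signal, as were 109 of the 201 lower genes. Few of these genes had a second measured probe. Among 8 such higher genes, all probes pointed the same way in 4 and passed 2-fold in 0. Among 14 such lower genes, these numbers were 8 and 4. Centring on the spike-in controls in place of the 75th percentile shifted every gene up by 1.00 on the log2 scale, giving 9964 higher and 24 lower genes, so each value here is relative to the bulk of the signal on its array.

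Most of the 12 lowest genes named by the rule, which leaves out the dimmest 25% of genes and clone or predicted names, were transcripts that carry no poly(A) tail. Rnu1b1 had a log2 signal of 5.93 on the MPDC-exo array and 2.72 on the KPC-exo array, at a probe on chromosome 3 from 96177970 to 96178029 (mm9). Rn28s1, a ribosomal RNA, was 8.18-fold lower, Rnu2-10, a U2 small nuclear RNA, was 7.01-fold lower, and the small nucleolar RNA Snord17 was 4.63-fold lower. Each of these had 1 probe. Rn18s, another ribosomal RNA, chosen outside the rule after its value was seen, was only 1.53-fold lower at 1 probe. Its log2 signal on the MPDC-exo array was 9.40, against 6.65 for Rn28s1, so the 8.18-fold value does not hold for ribosomal RNA in general. Among the histone genes, H4c4 was 3.27-fold lower, with log2 differences of -1.71 and -1.67 at its 2 probes, the brighter of which lies on chromosome 13 from 23673749 to 23673808. H1f4 was 3.40-fold and H2ac4 3.23-fold lower. Histone genes of 1 family are near-identical copies that probes may not separate, so the value of any single copy is uncertain. Prr7 was 3.13-fold lower. Spint2, which encodes a serine protease inhibitor, was 6.31-fold lower and Cd247, which encodes a chain of the T cell receptor complex, was 5.25-fold lower. In both genes the value rested on 1 probe, and the other 2 probes of Spint2 and the other 3 of Cd247 were not well above background on either array.

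**Figure D1:**
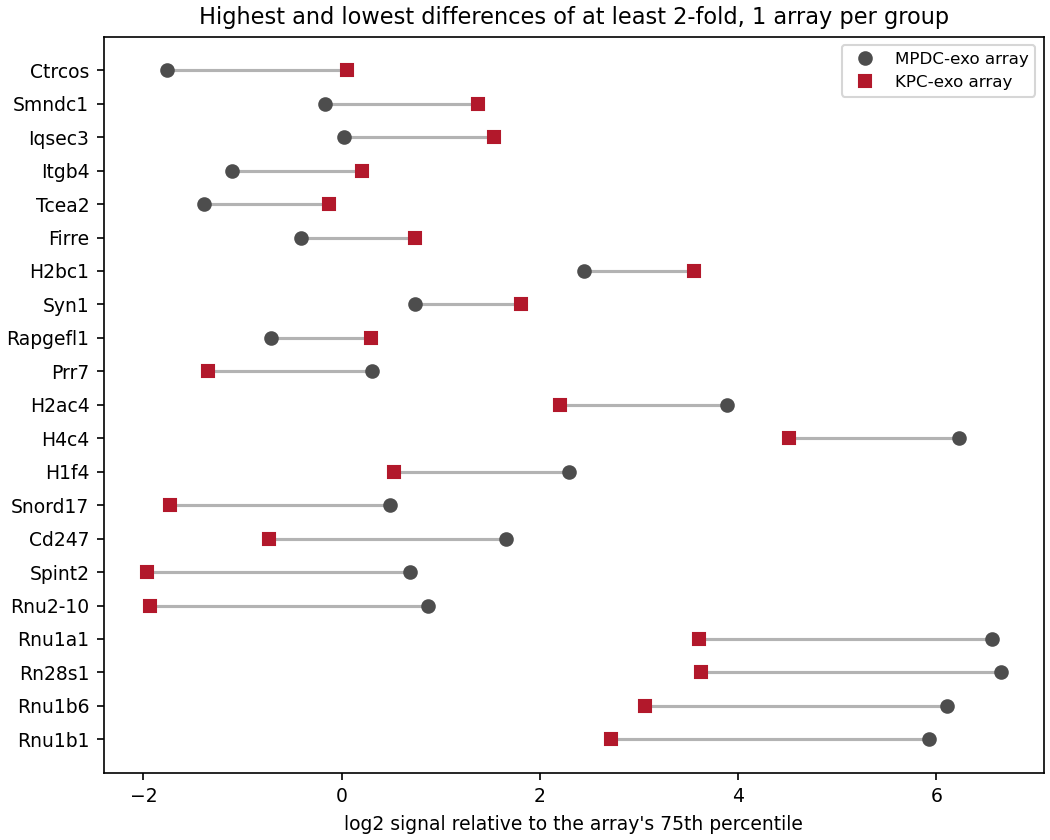
Log2 signal relative to the 75th percentile of each array (horizontal axis) for named genes at or above the 25th percentile of signal with the highest and lowest differences, at least 2-fold apart; circles are the MPDC-exo array and squares the KPC-exo array, 1 array per group. Rnu1b1 goes from 5.93 to 2.72, while Ctrcos, the highest of the genes shown, goes from -1.76 to 0.05.

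Among the genes the same rule names, the highest differences were smaller than the lowest. Of the 22 genes at least 3-fold higher, 21 were among the dimmest 25% and are not named here. Ctrcos, a noncoding transcript, was 3.51-fold higher on the KPC-exo array and Smndc1, which encodes a splicing factor, was 2.93-fold higher, at a probe on chromosome 19 from 53453980 to 53454039. Iqsec3 was 2.85-fold, Tcea2 2.39-fold and the histone gene H2bc1 2.16-fold higher. Itgb4, which encodes the beta 4 integrin subunit, was 2.47-fold higher at 1 probe, and its other 2 probes were not well above background on either array. The long noncoding RNA Firre was 2.22-fold and Syn1, which encodes a synaptic vesicle protein, 2.09-fold higher. Rapgefl1 was 2.01-fold, Dlk2 1.92-fold and Tjap1 1.92-fold higher. The 2 measured probes of Tjap1 ranged from 0.14 to 0.94 in log2 difference.

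Some genes were well above background on 1 array only. There were 1264 such genes on the KPC-exo array, 157 of them with a bound of at least 2-fold. On the MPDC-exo array there were 609, of which 175 had such a bound. A bound above 1-fold was reached by 1027 of the 1264 genes and by all of the 609. More probes were well above background on the KPC-exo array, 47.6% against 45.9%, so these gene counts do not compare the groups. Mpp4 was at least 9.72-fold higher on the KPC-exo array, and Cldn2, which encodes a tight junction protein, at least 7.70-fold. Abi3bp was at least 7.39-fold and the olfactory receptor gene Olfr141 at least 7.92-fold higher. In the other direction, Cyp2c68 was at least 10.5-fold, Olfr1484 at least 10.2-fold, Olfr1130 at least 8.78-fold and Itih4 at least 8.25-fold lower on the KPC-exo array. Each of these bounds rests on 1 probe, with a log2 signal on its brighter array from -0.33 to -0.72. Cyp2c68 and the 3 olfactory receptor genes had only 1 probe on the array. These are the largest bounds of many genes and allow for no spot error, so they are not firm minima.

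The cell cycle list had the lowest median of the 32 lists in the main values. Relative to all genes, endothelial and epithelial markers lay lower with normexp, fibroblast markers with background-flagged spots left out, an alternative chosen after seeing the data, and adipocyte markers in the mean of the members. The median log2 difference of its 41 measured members was -0.24, below all 10000 random lists of matched signal, whose central 95% ran from -0.02 to 0.17. On the KPC-exo array 36 members lay below the median of all genes, which was 0.06, and 4 were at least 1.5-fold lower. Cenpe, a kinetochore motor, was 1.71-fold lower, at a probe on chromosome 3 from 134936387 to 134936446. Nusap1, a spindle protein, was 1.55-fold lower, the centromere protein gene Cenpf 1.52-fold, and the phosphatase gene Cdc25b 1.51-fold, and with normexp these last 3 lay within 1.5-fold. The DNA replication list had a median of 0.00 over 42 members, at the 4.83 percentile of its random lists. Uhrf1, a DNA methylation maintenance gene, was 1.63-fold lower, while Pold1, Cdc6 and Pold2 had log2 differences of 0.57, 0.53 and 0.46. Markers of fibroblasts had a median of -0.15 over 14 members, at the 1.73 percentile, with 0 members 1.5-fold apart. The percentile was 3.24 with normexp, 4.00 with quantile normalization, 10.4 with the stricter filter and 4.12 for the mean of the members, all within the central 95%. S100a4 was 1.44-fold lower, Gsn 1.27-fold, Dpt 1.23-fold and Mfap5 1.21-fold. The log2 difference of S100a4 was 0 with quantile normalization and in the series value table. The 2 measured probes of Gsn had log2 differences of -0.35 and -1.13, with a mean of -0.74, past 1.5-fold.

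**Figure D2:**
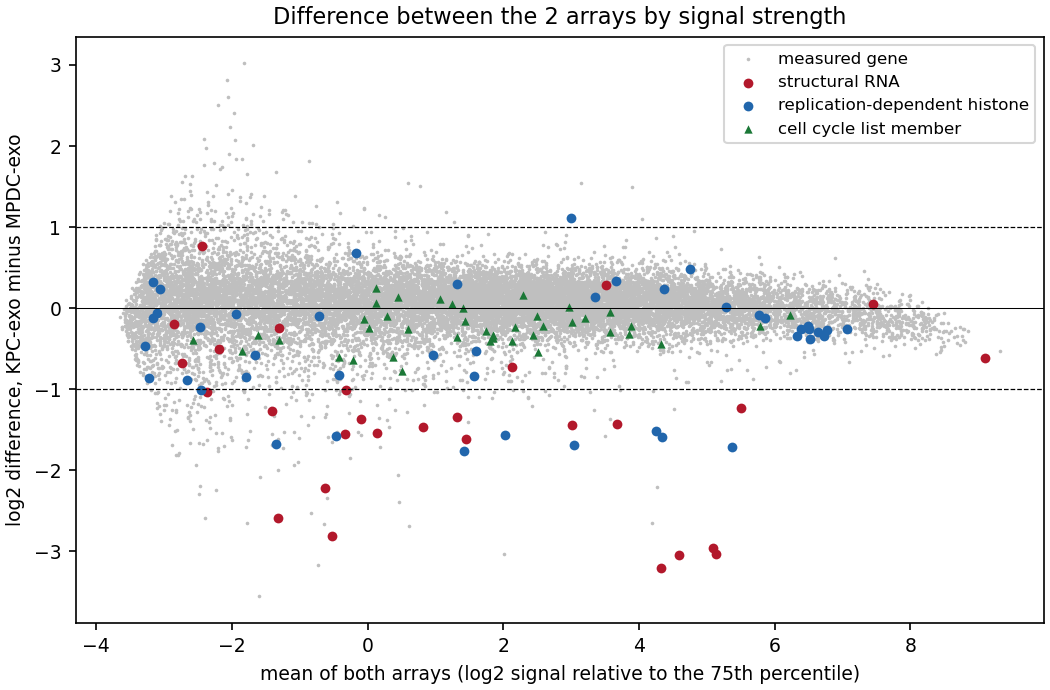
Log2 difference, KPC-exo minus MPDC-exo, against the mean log2 signal of both arrays for 16907 measured genes (grey), with structural RNAs (red), replication-dependent histones (blue) and cell cycle list members (green triangles); dashed lines mark 2-fold. Of 28 structural RNAs 19 lie at least 2-fold lower, while the 41 cell cycle genes lie mostly just under 0.

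Genes of cholesterol synthesis and uptake also lay lower, with a median of -0.10 over 24 members, at the 0.48 percentile, or 2.55 with background-flagged spots left out. Insig1, a sterol-regulated brake on the pathway, was 1.67-fold lower and was the 1 member past 1.5-fold, with a log2 difference of -0.74, or -0.57 with normexp. Hsd17b7 was 1.29-fold and Sqle, which encodes squalene epoxidase, 1.26-fold lower, while Nsdhl was 1.22-fold higher. The unfolded protein and integrated stress response list had a median of -0.05 over 37 members, at the 2.66 percentile, and lay below the central 95% in 3 alternatives. Its members Pdia4 and Hyou1, both endoplasmic reticulum chaperones, were 1.62-fold and 1.43-fold lower, Pdia6 was 1.22-fold lower and Edem1 1.33-fold higher. With background-flagged spots left out, Hyou1 had a log2 difference of -1.26 in place of -0.52, and Pdia4 had -0.55 in place of -0.70 with normexp.

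The sarcomere and excitation-contraction list had a median of 0.12 over 46 members, at the 99.3 percentile, with 1 member at least 1.5-fold higher and 0 lower. Its members split into 25 above and 21 below the median of all genes. The percentile lay within the central 95% in 4 alternatives, at 85.5 with normexp, 95.7 with loess, 95.9 with the mean over probes and 79.3 with background-flagged spots left out. Mb, which encodes myoglobin, was the 1 higher member at 1.52-fold, and lay under 1.5-fold in 5 alternatives, with log2 differences from 0.54 to 0.57. Myl2 was 1.42-fold and Myoz2 1.34-fold higher, while Ckm, which encodes muscle creatine kinase, was 1.35-fold lower. With background-flagged spots left out the list's median relative to all genes was 0.0055 in place of 0.064. Among myogenic regulators and fusion genes the median was 0.02 over 26 members, at the 27.8 percentile. Myod1 and Myog, the transcription factors of muscle differentiation, had log2 differences of -0.09 and -0.16. Cav3 had 0.50, Mef2c -0.42, Des -0.41 and Eya1 -0.40, and the 3 measured probes of Eya1 ranged from -0.40 to 0.46. The myosin gene Myh4 had 0.01 at its brightest probe and -1.19 at another measured probe.

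The FoxO target and atrophy list had a median of 0.10 over 27 members, at the 90.7 percentile, or 98.1 with normexp, and 0 members were 1.5-fold apart. Fbxo32 and Trim63, the ubiquitin ligases atrogin-1 and MuRF1, had log2 differences of -0.24 and 0.14, and Foxo1 had 0.10. Trim32, Klf15 and Eif4ebp1 had 0.54, 0.54 and 0.52, and Nedd4 had -0.54. Mstn, which encodes myostatin, was not well above background on either array. Proteasome subunits had a median of 0.06 over 33 members, at the 89.3 percentile, with Psmb2 1.56-fold higher at 3 probes that ranged from 0.56 to 0.80 in log2 difference, its value being 0.56, under 1.5-fold, with loess. Psmc4, Psme3 and Psmc1 had 0.28, -0.27 and -0.26, and the probes of Psmc4 ranged from -0.91 to 0.28. Autophagy and lysosome genes had a median of -0.02 over 30 members, at the 16.4 percentile, where Mcoln1 had -0.41, Becn1 0.37, Sqstm1 0.35 and Lamp1 -0.33.

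Insulin signalling and glucose uptake genes had a median of 0.01 over 29 members, at the 14.8 percentile, with 2 members at least 1.5-fold lower and 1 higher. Insr, the insulin receptor, was 1.95-fold lower at 1 measured probe on chromosome 8 from 3155472 to 3155531. Its other probe was not well above background on either array. The measured probe was dim, with log2 signals of -1.78 on the MPDC-exo array and -2.74 on the KPC-exo array. The log2 difference of Insr, -0.96, was -0.68 in an alternative. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, was 1.87-fold lower. Irs2, an insulin receptor substrate, was 1.51-fold higher, and lay under 1.5-fold in 5 alternatives of scaling, with log2 differences from 0.53 to 0.55. Gsk3b had a log2 difference of -0.54 at its brightest probe, with its 3 measured probes ranging from -0.66 to -0.03. Irs1 and the glucose transporter gene Slc2a4 had 0.03 and -0.17.

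Among lists of fuel use, fatty acid uptake and oxidation had a median of 0.13 over 27 members, at the 85.5 percentile. Eci1 was 1.56-fold higher, or 0.58 in log2 difference and under 1.5-fold with quantile normalization, and Slc27a4, Acaa2 and Acot2 had log2 differences of 0.48, 0.39 and 0.38. Pdk4, which restrains glucose oxidation, had 0.10. Triglyceride synthesis and lipid droplet genes had a median of 0.12 over 22 members, at the 87.0 percentile. Acacb, which encodes acetyl-CoA carboxylase 2, was 2.04-fold lower at 1 of its 3 probes, the others not being well above background. The log2 difference of Acacb, -1.03, was -0.83, under 2-fold, in an alternative. Mlxipl was 1.62-fold higher, or 0.56 in log2 difference with the mean over its probes. Mgll and Dgat2 had 0.37 and 0.35. Glycolysis had a median of -0.07 over 24 members, at the 16.8 percentile, with Pfkp at 0.42, Pgk1 at -0.38, Pgm2 at 0.38 and Ldha at -0.36. The 2 measured probes of Ldha had -0.36 and -0.89, and Pgk1 lay at -0.16 in an alternative. Oxidative phosphorylation had a median of 0.05 over 32 members, at the 89.8 percentile, with Sdhc at 0.56, Tfam at 0.53, Cox6c at -0.40 and Uqcrc2 at 0.34.

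Of the inflammatory lists, NF-kB targets, cytokines and chemokines had a median of 0.14 over 29 members, at the 97.1 percentile, and lay above the central 95% in 4 alternatives. Nos2 was 1.52-fold higher, its log2 difference of 0.60 being 0.27 with normexp, and Tnfaip2, Lif and Tlr2 had log2 differences of 0.43, 0.42 and 0.40, that of Lif being -0.032 with normexp background correction. Il6 had -0.19. The interferon response list had a median of 0.07 over 35 members, at the 66.9 percentile. Oas1g had a log2 difference of -0.56, Oasl1 0.33, Mx2 0.29 and Xaf1 0.29, and Oasl1 fell to 0.10 in an alternative. IL-6 and STAT3 response genes had a median of 0.03 over 19 members, at the 46.5 percentile, with Cebpb at -0.23, Il6ra at 0.23, Socs2 at 0.22 and Cebpd at -0.21. The probes of Il6ra ranged from -0.42 to 0.23 and those of Socs2 from -0.48 to 0.50.

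The stress and signalling lists lay within the central 95% of their random lists in the main values. Heat shock proteins had a median of -0.01 at the 27.7 percentile, with Hsp90aa1 at -0.46, Hsf2 at -0.42, Hspb3 at 0.40 and Hspa8 at -0.33. Oxidative stress and NRF2 targets had 0.01 at the 37.4 percentile, with G6pdx at 0.51, Hmox1 at -0.43, Osgin1 at 0.39 and Nfe2l2 at 0.36. For p53 targets and apoptosis genes the median was 0.02 at the 18.4 percentile, with Apaf1 1.61-fold higher, or 0.51 with normexp, Trp53 at 0.58, Bcl2 at -0.49 and Bax at -0.45. Hypoxia response genes had 0.03 at the 31.5 percentile, with Egln3 at 0.41, Bhlhe40 at 0.37, Stc2 at 0.35 and Ndrg1 at -0.32. Immediate early genes had 0.00 at the 11.1 percentile, with Nr4a1 at -0.50, Fosl1 at -0.44, Fosb at -0.36 and Egr2 at -0.27. Wnt and Notch signalling had 0.05 at the 42.4 percentile, with Tcf7 at 0.42, Hes6 at 0.37, Heyl at 0.34 and Jag1 at 0.30, the probes of Hes6 ranging from -0.64 to 0.37. Vesicle biogenesis and uptake genes had 0.03 at the 55.2 percentile, with Flot2 at 0.49, Cd63 at -0.47, Cav1 at -0.40 and Hgs at 0.35, the probes of Flot2 ranging from -0.78 to 0.49. Extracellular matrix and TGF-beta response genes had -0.02 at the 26.2 percentile, with Loxl2 1.63-fold lower at its brighter probe, its 2 probes ranging from -0.71 to -0.11, Mmp14 at -0.42, and probes that disagreed in sign in Fn1, from -1.68 to 0.88, and in Tnc, from -1.20 to 0.52. Cytosolic ribosomal proteins had -0.12 at the 36.5 percentile, or below the central 95% with no filter on dim probes, with Rps20 at -0.50, Rpl4 at -0.43, Rps12 at -0.37 and Rpl35 at -0.32, the probes of Rps12 ranging from -0.37 to 0.94. Measured probes also differed in sign in Cdc6, Sqstm1, Slc27a4, Xaf1, Mgll, Psme3 and Trim63. In at least 1 alternative Heyl fell to 0.079, Tcf7 to 0.22 and Stc2 to 0.16, and Cd63 lay at -0.17.

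**Figure D3:**
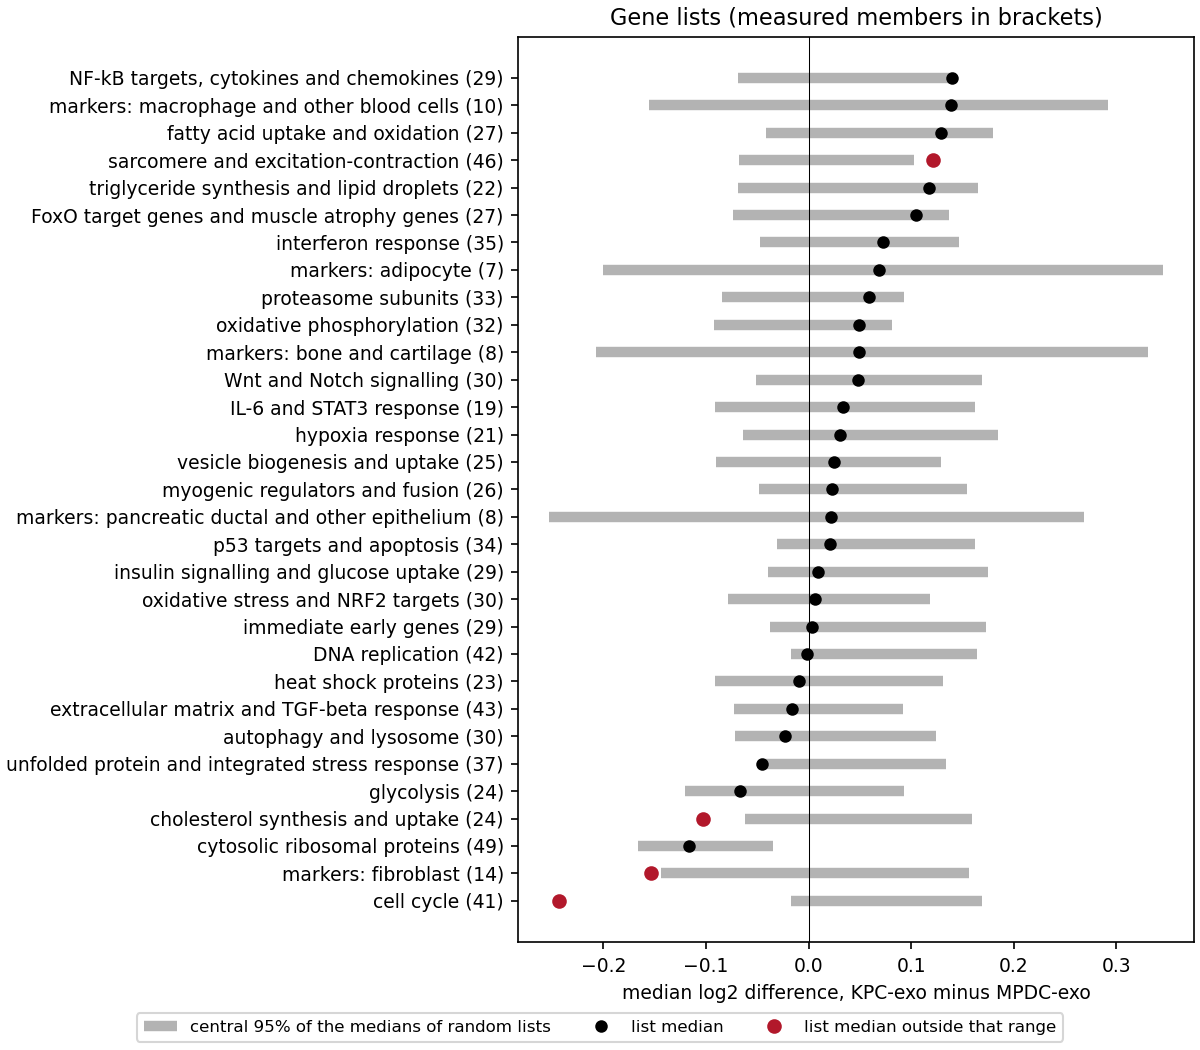
Median log2 difference, KPC-exo minus MPDC-exo, of each gene list (points, red where outside the range) against the central 95% of the medians of 10000 random lists matched on signal (grey bars), with measured members in brackets. The cell cycle, fibroblast marker and cholesterol lists lie below their bars and the sarcomere list above.

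Markers of other cell types were mostly near or below background. Of 26 markers of pancreatic ductal and other epithelium, the kind of cell that released the vesicles, 8 were measured, with a median of 0.02 at the 51.3 percentile. Spp1 had a log2 difference of 0.16, Sox9 -0.15 and Krt19 0.13, or -0.078 with normexp. Markers of macrophages and other blood cells had a median of 0.14 over 10 members, at the 71.3 percentile, with Cd74 1.87-fold and Cd68 1.55-fold higher and Csf1r 1.83-fold and Cd3e 1.70-fold lower. With normexp background correction the log2 difference of Cd74 was 0.23 in place of 0.90 and that of Cd68 0.43 in place of 0.63. Adipocyte markers had 0.07 over 7 members, at the 43.7 percentile. Among them Pck1, which encodes a gluconeogenic enzyme, was 4.90-fold lower at a dim probe on chromosome 2 from 172984307 to 172984366, its log2 difference being -2.29, or -1.33 with normexp, and Lep and Pparg had 0.34 and 0.15. Bone and cartilage markers had 0.05 over 8 members, at the 44.4 percentile, with Bglap at 0.33, Phex at -0.33, Col2a1 at 0.25 and Runx2 at 0.19, the probes of Runx2 ranging from -1.09 to 0.19. Bglap had -0.012 with normexp, and the adipocyte markers Lep and Pparg fell to 0.089 and 0.057 in an alternative. Of the endothelial markers 4 were measured, Egfl7 at -0.31, Kdr at -0.07, and Flt1 and Eng at 0.00. The reference genes had log2 differences of -0.19 for Gapdh, -0.35 for Actb, -0.07 for Hprt and 0.04 for Tbp, whose 3 measured probes ranged from 0.04 to 0.75. Signs turned for Gapdh, at 0.013, in the series value table, for Hprt, at 0.024, with normexp, and for Tbp, at -0.058, with loess. Actb kept its sign but ranged from -0.40 to -0.036 over the alternatives other than spike-in centring.

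In the main values, of 31 lists with a percentile, 3 lay below and 1 above the central 95% of their random lists. If list members varied independently, chance alone would put 1.55 outside. Members of a list may vary together, so chance can put more outside than that. In the simulated data 2 of 30 lists given no shift lay outside. That single run held independent spot noise only, so it cannot show how many would lie outside if members vary together. The positions of the lists in the data describe 2 arrays. They do not separate the exosome treatment from any other difference between the 2 cultures or their labelling reactions.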

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

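The alternatives that left out background flags, took the percentile over detected probes, or left out dim genes, RNAs without a poly(A) tail or genes without 2 agreeing probes were chosen after seeing the data. No paired analysis was possible because each group holds 1 array and no test was run. The counts of 123 higher and 201 lower genes stayed within 1.5 times under median centring, quantile, loess, the mean over probes, flagged spots kept, the series value table, the detected-probe percentile (107 and 220), background flags left out and RNAs without a poly(A) tail left out. They became 622 and 625 at 1.5-fold, 22 and 57 at 3-fold, 31 and 106 with normexp, 9964 and 24 with spike-in centring, 1600 and 1427 with no filter on dim probes, 7 and 44 with the stricter filter, 22 and 92 without the dimmest 25%, and 0 and 4 where each of at least 2 probes had to pass. The share of higher genes among those past 2-fold was 38.0% in the main values, 22.6% with normexp and 99.8% with spike-in centring, which moved the median of all genes from 0.06 to 1.06; list values here are relative to that median. Of 13 alternatives for the lists, 3 shift all genes alike and so cannot move a percentile. In the other 10 the cell cycle list lay below all random lists in each, the cholesterol list below the central 95% in 9, the fibroblast markers in 6 and the sarcomere list above it in 6. Lists within that range in the main values left it in some of these 10, the unfolded protein response list below in 3 and ribosomal proteins below in 1, NF-kB targets above in 4 and the FoxO and atrophy list above in 1. With normexp the medians were 0.14 for FoxO and atrophy, 0.0074 for autophagy, 0.057 for proteasome, 0.034 for myogenic regulators, -0.054 for glycolysis, 0.045 for oxidative phosphorylation, -0.035 for unfolded protein response, 0.021 for heat shock, 0.031 for oxidative stress, 0.042 for p53, -0.22 for cell cycle, -0.11 for ribosomal proteins, -0.0056 for extracellular matrix, 0.033 for immediate early genes, 0.025 for vesicles and -0.24 for epithelial markers. With no filter the median of all genes includes those not above background and is -0.15, so list values relative to it lie higher. The cholesterol list, -0.16 in the main values, had 0.044, while its own median stayed at -0.10 and its percentile was 0.51 against 0.48. Others were 0.15 for insulin signalling, 0.24 for FoxO and atrophy, 0.12 for autophagy, 0.21 for proteasome, 0.14 for myogenic regulators, 0.27 for sarcomere, 0.080 for glycolysis, 0.23 for oxidative phosphorylation, 0.28 for fatty acids, 0.18 for triglycerides, 0.22 for interferon, 0.26 for NF-kB, 0.15 for IL-6, 0.12 for unfolded protein response, 0.14 for heat shock, 0.14 for oxidative stress, 0.17 for p53, -0.089 for cell cycle, 0.14 for DNA replication, 0.030 for ribosomal proteins, 0.18 for hypoxia, 0.14 for extracellular matrix, 0.15 for immediate early genes, 0.25 for Wnt and Notch, 0.17 for vesicles and -0.028 for fibroblast markers. Ribosomal proteins, -0.17 in the main values, had -0.031 with quantile, -0.064 with loess, -0.12 with the mean over probes and 0.0054 with the series value table. Oxidative phosphorylation had 0.037 with loess. Oxidative stress genes had 0.0037 with loess, 0.024 with the mean over probes, 0.028 with the series value table and 0.014 with the mean of members. Glycolysis had -0.016 with the mean over probes, -0.0082 with the series value table and -0.060 with the mean of members, and triglyceride genes had -0.01 with the mean over probes. The stricter filter gave 0.11 for epithelial and 0.19 for bone markers. Background flags left out gave -0.028 for autophagy, 0.0055 for sarcomere, -0.093 for vesicles and -0.30 for fibroblast markers. The mean of members gave -0.024 for autophagy, -0.0096 for DNA replication, 0.049 for Wnt and Notch and -0.29 for adipocyte markers. Except where the set of genes itself differed, the cause was not tested. Of 165 named genes, spike-in centring shifted all, and under the other alternatives 24 of 1737 values moved by more than the spread between probes. Many of the 1737 could not move that far. Median centring and the detected-probe percentile shift all genes alike by a small amount, and the filters on dim probes keep the brightest probe's value. The mean over probes, which can move only genes with at least 2 measured probes, gave 12 of the 24. Of the 23 named genes at least 2-fold apart, 0 changed sign. By contrast, 18 genes with smaller differences, of at most 0.52, changed sign in at least 1 alternative. These were Tnc, Rps12, Runx2, Psmc4, Flot2, Hes6 and Il6ra with the mean over probes and Eya1 with background flags left out. Lif, Bglap, Krt19 and Hprt changed sign with normexp, and Gapdh with the series value table. Flt1, Eng, Irs1, Tbp and Myh4, near 0, did so with several, Myh4 having -0.59 with the mean over probes. S100a4, -0.53 in the main values, had 0 with quantile and in the series value table. Of 47 named genes at least 1.5-fold apart, 16 lay under 1.5-fold in at least 1 alternative, 9 of them with normexp. Signal over background limits the dim genes, where most of the higher genes lay.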

Other observations

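The classes of RNA below, and the tests on the histone genes, on signal strength and on the DNA replication list, were chosen after the results were seen; the tests on the slide position, GC content and probe position were written before their results were seen. Outside the fixed lists, the lower genes included most measured structural RNAs. Of 28 such RNAs, 22 were at least 1.5-fold lower on the KPC-exo array, 19 of them at least 2-fold. Only 1, Snord7, was at least 1.5-fold higher, and the median log2 difference of the 28 was -1.35. The 28 include the near-identical U1 copies Rnu1b1, Rnu1b6 and Rnu1a1, so they are not 28 separate measurements. Rn7sk, which holds back transcription elongation, was 2.73-fold lower, Rn7s1, of the signal recognition particle, 2.70-fold, Rpph1, of RNase P, 2.76-fold, and Rmrp 2.53-fold. The exceptions included Rn4.5s at 0.05 and Rnu12 at 0.28. Among 44 measured replication-dependent histone genes the median was -0.28, with 14 at least 1.5-fold lower and 2 at least 1.5-fold higher. The H4 genes H4c11 and H4c14 were 2.98-fold and 2.86-fold lower, whereas H2bc3 and H2bc14 had log2 differences of 0.48 and 0.24.

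The mitochondrial genome showed a smaller difference, apart from ND6. Of its mRNAs, 10 other than ND6 were measured, with a median of -0.26, at the 0.09 percentile of random sets matched on signal. These values are given in the main scaling only, and most of these probes are bright. The ribosomal proteins, also bright, lay closer to all genes with quantile and loess normalization, so the size may depend on scaling. ATP8 had a log2 difference of -0.55, COX1 -0.30 and ND1 0.02. ND6, the mRNA encoded on the other strand, was 2.45-fold lower at 1 probe. Its log2 difference of -1.29 lay near the median of the structural RNAs, -1.35.

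For the structural RNAs, a trend with signal strength and a local defect of the slide were argued against. Their median was at percentile 0 among 10000 random sets of the same signal strength, whose central 95% ran from -0.07 to 0.17. The class was chosen after its low values were seen, so the percentile alone is not support. The range of the random sets shows that genes of that signal strength were not as low in general. The measured spots around the probes of the structural RNAs had a median log2 difference of 0.0075, close to that of all genes. A candidate explanation is that RNAs without a poly(A) tail were labelled less well in the KPC-exo reaction; the median of the replication-dependent histones minus that of the replacement variants was -0.25, with a bootstrap interval over genes from -0.54 to 0.05. The interval takes histone copies that probes may not separate as independent genes, so it understates the spread. Fewer cycling cells, a hypothesis taken up below, could lower the replication-dependent histones too, so this contrast cannot test labelling alone. The explanation stays open, and it cannot be told apart from an effect of the exosomes with 1 labelling reaction per group.

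For the cell cycle genes, the base composition and the place of the probes were argued against. The list median minus the lower bound of the central 95% of random sets was -0.24 for sets matched on signal and probe GC content and -0.22 for sets matched on signal and probe start, and 0 of 10000 sets were as low in either case. Fewer cycling cells in the KPC-exo culture could account for the pattern as a hypothesis. The DNA replication list lay at the 4.83 percentile of its random lists, with members on both sides of 0, which does not decide it. A difference between cultures unrelated to the exosomes was not tested and stays open.

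Before centring, the 75th percentile of the mouse probes was 1.68-fold higher on the KPC-exo array, while the mean of 7 spike-in probes was -0.25 on the log2 scale relative to the MPDC-exo array. Background flags marked 6334 spots on the KPC-exo array and 2296 on the MPDC-exo array.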
